A study of Mus musculus with 4 samples.

How the data were processed

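Single-cell RNA was measured in 4 libraries from mouse trachea, 1 library for each combination of region (dorsal or ventral) and genotype (control or Ctnnb1 knockout). Per the labels, every mouse carried a tamoxifen-dependent Cre in P63-expressing basal cells, a Dre recombinase placed at Ki67 behind a stop that Cre removes, and a GFP gene at Rosa26 behind a stop that Dre removes. Controls had 1 floxed Ctnnb1 allele and knockouts had both alleles floxed. Tracheae were collected 10 days after tamoxifen and dissociated with papain, and libraries were made with a 10x Genomics GEM-X 5′ kit. The number of mice behind each library, the hour of collection and the deleted Ctnnb1 exons are not given in the sources used here.

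The deposited files held raw UMI counts per gene and barcode for 33697 features, an eGFP sequence among them. They were made with Cell Ranger 10.0.0 on genome GRCm39, per the submitters' processing notes. The annotation release and the filters used for calling cells are not given in the sources used here. Every class was assigned from the counts.

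Barcodes with at least 500 genes and at most 15% mitochondrial UMIs were kept. This removed 615, 1360, 520 and 930 barcodes for few genes and 101, 46, 39 and 12 for mitochondrial UMIs in the control dorsal, control ventral, knockout dorsal and knockout ventral libraries. Doublets were called per library with Scrublet (scanpy 1.11.5) at its automatic threshold, or at 0.4% per 1000 barcodes where the automatic call lay outside 0.5% to 20%. The automatic threshold was used in the dorsal libraries (297 control and 56 knockout cells removed, 2.24% and 0.905%). The fixed rate was used in the ventral libraries (497 and 235 cells, 5.10% and 3.49%), where the automatic calls were 0.0821% and 0.0743%. Cells kept numbered 12949, 9247, 6129 and 6491.

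Counts were scaled to 10000 per cell and logged. Up to 2000 variable genes were reduced to 30 principal components and clustered from 20 neighbours with Leiden at resolution 1 (scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2). Libraries were clustered together without integration, because library and group are the same. Mitochondrial, ribosomal protein, haemoglobin, immunoglobulin and sex-linked genes, eGFP and Ctnnb1 took no part in clustering. The 38 clusters were named from 33 marker lists, and the epithelial cells were clustered again into 23 clusters and named in the same way. A name needed a mean marker score of at least 0.5 of the highest cluster and at least 3 markers in 10% of the cells. No other list could have more markers among the 10 leading genes of the cluster. A cluster with low UMIs for its libraries also needed a marker of its own list there. Clusters that failed were left unnamed.

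UMIs were summed per class and library and expressed as CPM, a share of all UMIs of that class. Shares have exact Clopper-Pearson intervals, ratios of summed counts have conditional binomial intervals, and all are at 95% (scipy 1.17.1). These cover counting error only, and cells are not replicates. With 1 library per group no test was run and no p-value or count of changed genes is given. A share of 0 is given with the limit that 3 counts allow.

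Genes named in the text followed a rule: at least 20 CPM and at least 50 UMIs in 1 library of each pair, and a level of at least 10% of the highest other class of at least 50 cells. Genes under that last level were set aside as possible free RNA. Mitochondrial, ribosomal protein, haemoglobin, immunoglobulin, sex-linked and handling genes were not ranked. For each comparison the 10 highest genes each way were taken by the smaller interval bound over both pairs, among genes on the same side in both. Up to 5 genes per region and direction were taken as limited to 1 region, with a bound of at least 2-fold in that region and a ratio within 1.25-fold, or on the other side, elsewhere.

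The 17 fixed gene lists were basal identity, Wnt targets, Wnt ligands and secreted regulators, junctions, matrix adhesion, proliferation, hillock and squamous, secretory, multiciliated, Notch, BMP and TGF-beta, p53 and senescence, interferon response, class II antigen presentation, epithelial alarm genes, handling, and regional transcription factors. A member was measured with at least 10 UMIs in 1 of the libraries compared. Each list is given as its median log2 ratio (0.5 UMIs added to each count) with its percentile among 10000 random lists of the same size matched on mean expression in 20 bins. That percentile is a description of these libraries. Examples were the members with the furthest interval bounds, and any other gene was chosen after its values were seen. Some genes that met these rules are not reported here.

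For shares of cycling and of reporter-high cells, each cell was thinned to 8000 UMIs and shallower cells were left out. A cell counted as cycling with UMIs of at least 3 proliferation genes. The comparison of reporter-high cells (at least 5 eGFP UMIs) with reporter-low cells (at most 1) was added after the data had been seen. Also added then were the mitotic gene count (at least 2 of 8 genes), the surface epithelium as denominator, the clock genes, the transcript length checks and a check that thinned the eGFP UMIs of control cells by 1 factor. Transcript lengths were those of the longest GENCODE M21 (GRCm38) transcript, matched on gene ID only, and 99.7% of the 6265 genes compared in dorsal basal-like cells had one. For the length checks, random lists were matched in 5 bins each of expression and length.

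The calculations were tested on simulated data for the dorsal knockout to control comparison in basal-like cells, with 6173 genes of which 200 were changed. At 1.25-, 1.5- and 2-fold, 100% of the changed genes had their interval on the right side of 1, and 94.8%, 95.0% and 95.3% of all genes had an interval that held the true ratio. All simulated counts were drawn with counting error only, as the intervals assume. They check the calculation and say nothing about variation between libraries. Of 200 unchanged lists of genes, 3.5% fell outside the middle 95% of random lists matched on expression and 2% outside that of lists matched on expression and length. With a simulated length trend, 100% of 200 unchanged lists of long genes fell outside the former and 3.5% outside the latter.

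The fixed lists, marker lists, gene rule, filters and main comparisons were set before the data were examined. Alternatives set then were a stricter filter (1000 genes and 5% mitochondrial UMIs), doublets kept, Leiden resolutions 0.5 and 2, naming of each cell by its own markers and median-of-ratios size factors. Also set then were thinned cells, unthinned cycling shares, at least 2 proliferation genes, list members with at least 50 UMIs, and cells with no UMI of a proliferation gene. Software also included Python 3.11.15, numpy 2.4.6, pandas 2.3.3, anndata 0.12.19 and matplotlib 3.10.9.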

Results

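Basal-like, secretory-like and ciliated-like epithelial cells and a large fibroblast-like class were found in all 4 libraries. The libraries of control dorsal, control ventral, knockout dorsal and knockout ventral trachea held 13962, 11150, 6744 and 7668 barcodes, with medians of 14350, 11708, 14544.5 and 10902 UMIs. After filtering, 34816 cells remained, 20044 of them epithelial. Values below follow that order of libraries unless stated. Each group was a single library, so every difference lies between libraries and its interval covers counting error only.

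Ctnnb1 RNA was lower in basal-like cells of both knockout libraries, at 0.746 (0.727 to 0.765) of the control level dorsally and 0.817 (0.791 to 0.844) ventrally. The levels were 279, 281, 208 and 229.6 CPM. Secretory-like cells held 0.847 and 0.802 of the control level. Fibroblast-like cells, which should not express the Cre, had nearly the same shift, and the ratio in basal-like cells relative to fibroblast-like cells was 0.991 dorsally and 0.962 ventrally. Reporter-high basal-like cells of the knockouts held 0.977 and 1.12 of the Ctnnb1 level of reporter-low cells, against 0.983 and 1.09 in the controls. Transcripts are counted from tags near 1 end, so a tag outside the deleted part would check nothing, and deletion could not be verified from these counts.

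Basal-like cells made up more of all epithelial cells in the dorsal than in the ventral control library and most in the dorsal knockout library, an order that depends on which cells are counted as epithelium. They were 39.5% (38.6 to 40.5), 34.2% (32.8 to 35.6), 53.1% (51.4 to 54.8) and 36.7% (34.9 to 38.6) of epithelial cells, from 3706, 1555, 1790 and 1013 cells. The dorsal minus ventral difference in controls was 5.32 points (3.60 to 7.02), and knockout minus control was 13.5 points (11.5 to 15.5) dorsally and 2.51 points (0.231 to 4.81) ventrally. Ciliated-like cells took less of the epithelium in both knockouts, with shares of 16.2%, 12.9%, 4.00% and 7.54%. Secretory-like cells made up 32.8%, 24.9%, 38.1% and 21.4%. Outside the epithelium, chondrocyte-like cells were 2.98%, 5.26%, 0.604% and 4.21% of all cells kept. Thyroid-like cells were 3.30% of the control and 0.293% of the knockout ventral library. The mix of tissue recovered was therefore not alike in controls and knockouts, and differences between genotypes cannot be separated from it.

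Hillock-like cells were almost confined to dorsal tissue, and gland-like cells were found only in ventral tissue. Hillock-like cells were 8.55% and 3.53% of the dorsal epithelium of controls and knockouts and 0.484% and 0.435% of the ventral epithelium. These shares, from 801, 22, 119 and 12 cells, depend on the clustering. At Leiden resolution 2 only 160, 4, 28 and 3 cells were named hillock-like, and at resolution 0.5 no cluster was. Gland-like cells were 13.4% and 17.2% ventrally and absent dorsally, with limits of 0.0320% and 0.0889%. Unnamed clusters took 2.64%, 12.9%, 0.978% and 14.9%, so ventral shares are lowered by gland-like and unnamed cells. Of the surface epithelium alone, basal-like cells were 40.7%, 47.2%, 53.8% and 55.5%, which turned the dorsal to ventral order in controls (-6.52 points), put the ventral knockout library highest and gave knockout minus control ventrally as 8.32 points. Tuft-like cells (0.160%, 0.638%, 0.119% and 0.544%), ionocyte-like cells (0.0320%, 0.176%, 0.148% and 0.544%) and neuroendocrine-like cells (at most 0.725%) were rare everywhere.

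**Figure D1:**
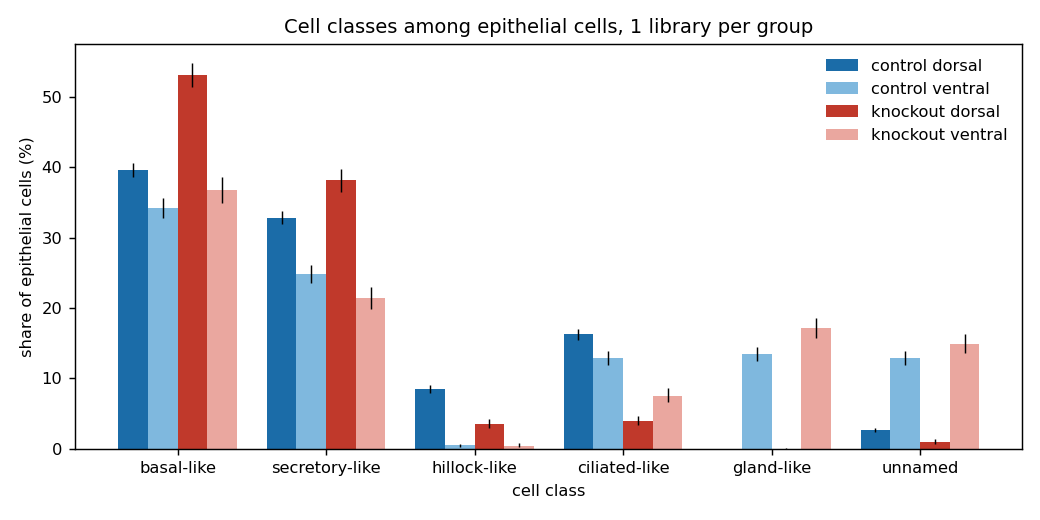
Share of epithelial cells in each class (vertical axis, %) for basal-, secretory-, hillock-, ciliated- and gland-like cells and unnamed clusters (horizontal axis). Colours mark the 4 libraries, control and knockout, dorsal and ventral. Error bars are 95% intervals from counting error.

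Dorsal basal-like cells held far more RNA of cell division genes and of hillock genes than ventral ones, in controls and in knockouts. Ventral basal-like cells held more of the transcription regulators Eya4 and Isl1, of Notch pathway genes and of interferon-response genes. Across 6381 genes the dorsal to ventral ratios of the control and the knockout pair, which share no library, had a Pearson correlation of 0.70, although genes are not independent replicates. Other classes shared part of the regional difference. In controls the basal ratios correlated with those of secretory-like (0.76), ciliated-like (0.52), fibroblast-like (0.50), macrophage-like (0.44), chondrocyte-like (0.30) and lymphatic endothelial cells (0.29). In knockouts the correlations were 0.83, 0.61, 0.78 and 0.57 with secretory-, ciliated-, fibroblast- and macrophage-like cells. The basal-like cells came mostly from 3 clusters: 71.1% of the control dorsal cells lay in cluster 0, 89.1% and 84.4% of the ventral cells in cluster 1, and 85.4% of the knockout dorsal cells in cluster 2. The mainly ventral cluster 1 also held 9.90% of the control dorsal cells but 1.56% of the knockout dorsal cells. Aqp3 and Abi3bp were the top genes of clusters 1 and 2. Further leading genes included Egr1, Fos, Dnajb1 and Jun in cluster 1, and Hspb1, Rps19, Rps28, Rps12 and Rps27 in cluster 2.

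Among genes higher in dorsal basal-like cells were the tubulin-binding Tppp3 at 11.2-fold (10.6 to 11.9) in controls and 14.03-fold (13.0 to 15.2) in knockouts (at 12.4% of the level in ciliated-like cells), and Porcn, which encodes the acyltransferase needed for Wnt secretion, at 8.31-fold (7.91 to 8.74) and 6.70-fold (6.34 to 7.10). Coagulation factor F5 was 11.2- and 15.6-fold higher, Serpinb10 19.7- and 12.9-fold, Clca3b 15.7- and 8.77-fold and Upk3bl 5.36- and 7.35-fold. The division genes Ube2c (7.57- and 10.4-fold), Cenpf (7.80 and 9.10) and Anln (6.15 and 5.67) and the tropomyosin gene Tpm2 (6.07 and 5.55) completed the group. On the ventral side Eya4 stood out, with a dorsal to ventral ratio of 0.103 (0.0942 to 0.112) in controls and 0.0740 (0.0650 to 0.0838) in knockouts. Isl1 was at 0.207 (0.191 to 0.225) and 0.193 (0.174 to 0.213) and was also ventral in fibroblast-like cells, at 0.0623 and 0.0331. The proton pump subunit gene Atp6v1b1 (0.135 and 0.173), the adhesion genes Cadm2 (0.187 and 0.188) and Lrrc4c (0.186 and 0.148), Chst9 (0.187 and 0.142) and Tmtc1 (0.184 and 0.128) were lower dorsally as well. So were Cyp4a12b (0.147 and 0.0775), Tgtp1 (0.186 and 0.102) and Tgtp2 (0.1999 and 0.0769), whose near-identical relatives could share reads. Gland genes such as Lyz1, Dmbt1, Lipf and Tff2 were set aside as possible free RNA of ventral glands.

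The proliferation list was far higher dorsally, with a median log2 ratio of 1.73 in controls (29 of 30 genes above 0, percentile 100 of random lists) and 1.62 in knockouts (30 of 30). Ccnb1 (6.94- and 15.5-fold), Mki67 (3.61 and 3.16) and Top2a (4.83 and 3.62) were among its members. Hillock and squamous genes were at 2.20 (16 of 17 above 0) and 1.52 (15 of 16), with Sprr2a3 (18.8- and 21.7-fold), Krt13 (13.9 and 31.5) and Krt6a (8.31 and 4.99), and with doublets kept at 1.21 and 0.80. This list was also higher dorsally in fibroblast-like cells (1.29 and 0.63), so part of it could be free RNA of hillock-like cells, although Krt13 stood at 92.8 CPM in control dorsal basal-like cells and at 0.570 in fibroblast-like cells of that library. With doublets kept, a cluster with basal and hillock genes (Krt5, Krt17, Krt4 and Ecm1) among its leading genes was left unnamed. It held 539, 8, 59 and 1 cells, so the list could also depend on whether such cells count as basal-like. Multiciliated genes were slightly higher (0.37 and 0.40, percentile 99.98 in both pairs), led by Tppp3, Cfap126 (3.03- and 4.72-fold) and Rsph1 (2.61 and 3.18). They were higher in control dorsal fibroblast-like cells as well (0.26), where they should be free RNA, but lower in knockout dorsal ones (-0.19). Taking off the length trend left 0.15 in knockout basal-like cells.

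Interferon-response genes were lower in dorsal than in ventral basal-like cells, with medians of -0.63 (24 of 25 below 0) and -0.61 (20 of 25), and examples in Iigp1 (0.132 and 0.0968) and Igtp (0.293 and 0.383). Notch genes had medians of -0.54 in both pairs (14 of 15 below 0 in each), with Dll1 at 0.575 and 0.387 and Notch1 at 0.616 and 0.519. Wnt targets were at -0.34 and -0.42 (percentiles 1.66 and 5.48), with the stem cell receptor gene Lgr5 at 0.169 and 0.163 and Tnfrsf19 at 0.530 and 0.511. Wnt ligands and secreted regulators were at -0.40 and -0.62 (percentiles 3.12 and 0.505; -0.37 in knockouts at resolution 0.5), led by Rspo3 (0.113 and 0.263). Regional transcription factors were at -0.38 and -0.52 (-0.35 with size factors in knockouts), with Isl1, Tbx3 (0.107 in controls) and Sox9 (0.121 in knockouts) ventral and Osr1 dorsal (3.02- and 2.63-fold). Class II genes were at -0.59 and -0.45 (percentiles 21.3 and 20.2; Cd74 0.324 and 0.374), and the control median ranged from -1.16 to -0.41 over the alternatives. Handling genes were lower dorsally, at -0.22 (-0.10 with size factors) and -0.75, with Egr1 at 0.542 and 0.375.

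Junction genes stood on opposite sides in controls and knockouts. They were at 0.22 in controls (19 of 23 above 0, percentile 97.8; Dsg3 5.84-fold, Cldn1 4.44-fold) and at -0.44 in knockouts (19 of 23 below 0, percentile 0.59, and -0.26 with size factors; Ocln 0.436, Cdh1 0.477). Long transcripts were lower in dorsal than in ventral knockout cells (Spearman correlation of ratio and length -0.52), and among random lists matched on length the knockout junction list was at percentile 9.67, inside the middle 95%, as were Wnt targets at 17.3 (-0.11 with the length trend taken off) and Notch genes at 2.91. Matrix adhesion genes were at 0.18 and -0.31 (percentiles 90.7 and 9.26), with Col17a1 at 1.81-fold in controls and Col4a1 at 0.271 in knockouts, and taking off the length trend turned the knockout median to 0.03. Basal identity genes were at 0.04 and -0.26 (percentiles 36.4 and 6.03) and p53 and senescence genes at 0.01 and -0.38 (39.3 and 5.995, or 2.34 in knockouts matched on length; Sesn2 0.548 in knockouts). Alarm genes were at 0.20 and -0.07 (97.9, or 95.3 matched on length, and 66.6), turning to -0.0758 in controls with doublets kept, with the growth factor gene Ereg 11.8-fold higher dorsally in controls. Over the alternatives the knockout median of the alarm list ranged from -1.17 to 0.10. Secretory genes (0.00 and 0.06) and BMP and TGF-beta genes (-0.07 and -0.16; Id1 0.403 in controls) had no difference beyond random lists. The secretory median in knockouts turned to -0.34 with the length trend taken off, and the list was at percentile 13.8 of random lists matched on length. Size factors shifted every dorsal to ventral ratio by 0.11 log2 in controls and 0.18 in knockouts, which turned the BMP and TGF-beta list in both pairs and the alarm list in knockouts.

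**Figure D2:**
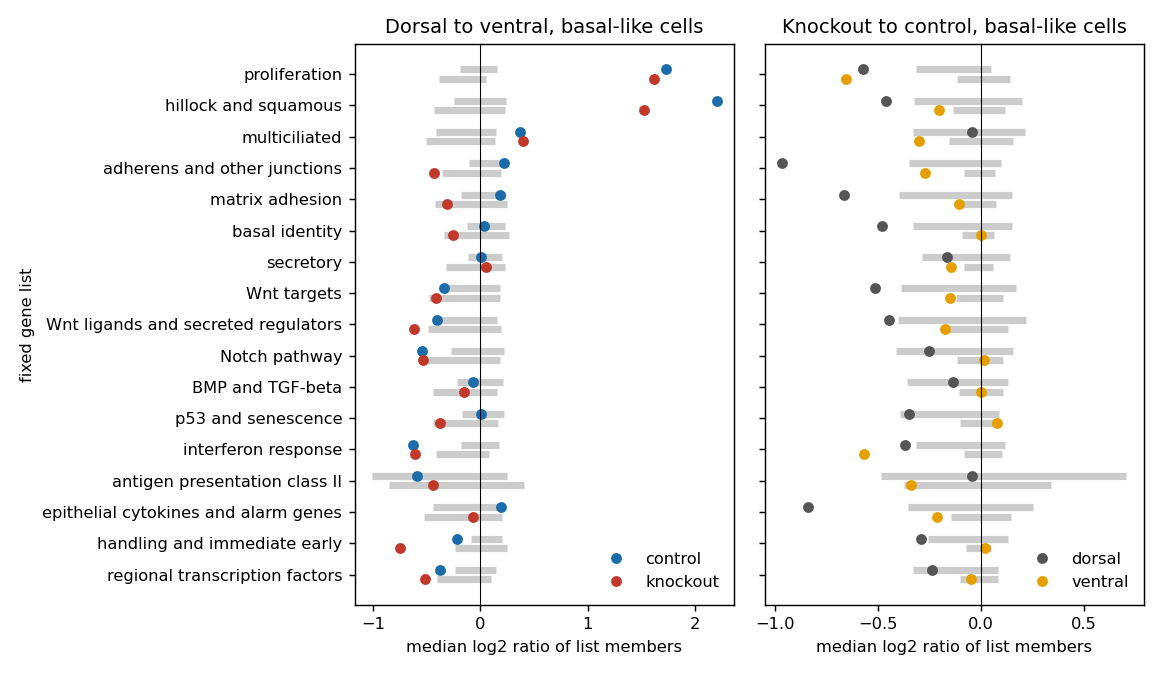
Median log2 ratio (horizontal axis) of the 17 gene lists (vertical axis) in basal-like cells. The left panel gives dorsal to ventral ratios in the control and the knockout pair, and the right panel gives knockout to control ratios in dorsal and ventral tissue. Grey bars hold the middle 95% of random lists matched on expression, the upper bar for the first point and the lower bar for the second. Points have no error bars because each group is 1 library.

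Cells with mitotic gene RNA were more frequent among dorsal than ventral basal-like cells, and less frequent in the dorsal knockout. With cells thinned to 8000 UMIs, at least 2 of 8 mitotic genes were found in 5.52% (4.78 to 6.34), 1.58% (1.02 to 2.35), 2.39% (1.72 to 3.23) and 0.813% (0.352 to 1.60) of 3404, 1516, 1717 and 984 basal-like cells. These were 188, 24, 41 and 8 cells, and the intervals of the ventral control and knockout overlapped. In fibroblast-like cells the shares were 0.336%, 0.658%, 0.562% and 0.376%. This count of mitotic genes was chosen after the planned share was seen. The planned share, at least 3 genes of the whole proliferation list, was 33.0%, 36.9%, 35.6% and 36.1%, and without thinning 59.2%, 79.0%, 72.7% and 80.2%. Its dorsal minus ventral difference was -3.85 points (-6.80 to -0.936), and knockout minus control was 2.62 points (-0.157 to 5.43) dorsally and -0.796 points (-4.70 to 3.14) ventrally. Fibroblast-like cells reached 15.6%, 18.5%, 17.2% and 20.3% by the same rule, and the share runs against the summed RNA of Mki67 and Top2a, so no order is read from it. Median depths were 14984, 22723, 20052.5 and 23019 UMIs in basal-like and 8803, 11707, 10428 and 10312.5 in fibroblast-like cells, and thinning left out 302, 39, 73 and 29 shallow basal-like cells.

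Basal-like cells of both knockout libraries held less RNA of junction, proliferation and interferon-response genes than controls. Dorsally the junction, matrix adhesion, Wnt target and basal identity lists were far lower, and ventrally the same lists were nearer to the controls. Tsc22d3 and Fkbp5 were higher in both knockouts, and the clock repressor gene Nr1d1 was lower. Dorsal and ventral knockout to control ratios had a Pearson correlation of 0.44 across 6381 genes, which are not independent replicates. Much of the dorsal difference was shared by other classes: across genes the basal ratios correlated with those of secretory-like (0.88), hillock-like (0.81), fibroblast-like (0.76) and macrophage-like cells (0.57) of the same libraries, against 0.56, 0.42 and 0.27 ventrally for secretory-like, fibroblast-like and macrophage-like cells.

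Named genes higher in both knockouts were led by Akr1c14 (2.93-fold dorsally, 2.21-fold ventrally), the protease inhibitor Slpi (4.12, 3.70 to 4.60, and 2.06, 1.92 to 2.21), haptoglobin Hp (1.99 and 2.61) and Tsc22d3 (3.11, 3.03 to 3.19, and 1.83, 1.77 to 1.88). Arl4d (6.34 and 1.78), Fkbp5 (1.71 and 2.05), the collectin gene Sftpd (1.58 and 1.70), Chd9 (1.61 and 1.64), Gm47283 (2.06 and 1.79) and Gm16867 (1.75 and 2.16) followed. In fibroblast-like cells Tsc22d3 (2.17 and 1.68) and Fkbp5 (1.95 and 2.05) had similar ratios. Among lower genes were Nr1d1 (0.140, 0.129 to 0.152, and 0.424, 0.392 to 0.458), the chemokine gene Cxcl10 (0.175 and 0.351) and Gm56626 (0.119 and 0.0923), which were also lower in fibroblast-like cells (Nr1d1 0.167 and 0.318, Cxcl10 0.373 and 0.605, Gm56626 0.103 and 0.122). The actin-associated gene Cald1 (0.249 and 0.545), the mucin gene Muc16 (0.496 and 0.479), Ppargc1a (0.403 and 0.459), Sema3e (0.336 and 0.511), Edn1 (0.528 and 0.563) and Aebp2 (0.476 and 0.564) were lower too. Cald1 was not lower in fibroblast-like cells (1.26 and 1.01).

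Junction genes lay below nearly all random lists in both knockouts, at -0.97 dorsally (0 of 23 genes above 0) and -0.27 ventrally (5 of 23), with percentile 0 in both regions. Cldn1 (0.135 and 0.253), Ocln (0.296 and 0.723) and the E-cadherin gene Cdh1 (0.486 and 0.776), whose protein binds beta-catenin, were lower in both. Matrix adhesion genes were at -0.67 and -0.11 (percentiles 0.01 and 2.33, the latter 3.555 matched on length; -0.42 dorsally with cells named singly), with the laminin gene Lama3 at 0.442 and 0.528. Basal identity genes were at -0.48 dorsally (percentile 0.12), with Krt17 at 0.424 and Dst at 0.492, and at 0.00 ventrally (percentile 67.0), with Trp63 at 1.24. Long transcripts were lower and ribosomal protein RNA higher throughout the dorsal knockout library. In basal-like cells the Spearman correlation of the ratio with transcript length was -0.47, against -0.46 in fibroblast-like cells and -0.11 in ventral basal-like cells, and ribosomal protein genes took 15.6%, 16.9%, 20.1% and 16.7% of basal UMIs. The nuclear RNA Neat1 was at 289.7, 1009, 105 and 651 CPM in basal-like and 288, 485, 77.7 and 292 CPM in fibroblast-like cells, and mitochondrial genes took 2.03%, 1.87%, 2.72% and 2.10% of basal UMIs. Against random lists matched on length, the dorsal junction list was at percentile 0, matrix adhesion at 0.26 and basal identity at 0.15. With the length trend taken off, their medians were nearer to 0, at -0.58, -0.29 and -0.25.

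Wnt targets were lower in both knockouts, at -0.52 dorsally (14 of 19 below 0, percentile 0.3, or 1.13 matched on length; -0.24 with the length trend taken off) and -0.15 ventrally (13 of 19, percentile 1.07). Myc (0.302 dorsally), Apcdd1 (0.561 and 0.594) and Dkk3 (0.405 and 0.731) were examples, while the direct target Axin2 was higher (1.73 and 1.26) at a level of at most 1.01 CPM. Wnt targets were lower in fibroblast-like cells too (-0.83 dorsally, 21 of 22 below 0, and -0.22 ventrally, 18 of 22), with Ccnd1 at 0.367 and Cd44 at 0.448 and 0.693. Wnt ligands and secreted regulators were at -0.45 and -0.17 in basal-like cells (percentiles 1.44 and 1.54), with Wnt5b at 0.410 and 0.661 and Wnt7b at 0.567 dorsally. Their dorsal median was -0.17 with the length trend taken off and turned to 0.0101 with cells named singly, so this list gave no firm dorsal difference.

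Proliferation genes were at -0.57 dorsally (26 of 30 below 0, percentile 0.01) and -0.66 ventrally (23 of 30, percentile 0) in knockouts, with Mki67 at 0.455 and 0.519, Cenpf at 0.496 and 0.425 and Cenpa at 0.521 and 0.404. With cells named singly the medians were -0.17 and -0.41. Fibroblast-like cells had no such difference (0.09 and -0.05). By the mitotic gene count only 24 control and 8 knockout ventral basal-like cells were found, so the ventral list could rest on few cells. Hillock and squamous genes were at -0.46 and -0.20 (percentiles 0.28 and 0.25), with Krt6a at 0.218 and 0.362, and they were lower in fibroblast-like cells as well (-0.65 and -0.32), so less free RNA of hillock-like cells could add to this. At Leiden resolution 2 the hillock medians were -0.16 and -0.0300, nearly 0 ventrally. At that resolution a cluster with basal and hillock genes among its leading genes, of 535, 11, 57 and 0 cells, was left unnamed. Interferon-response genes were at -0.37 (22 of 25 below 0, percentile 0.765; -0.21 with cells named singly) and -0.57 (24 of 25, percentile 0), with the antiviral genes Ifit3 at 0.106 and 0.113 and Iigp1 at 0.277 and 0.379, and they were lower in fibroblast-like cells as well (-0.52 and -0.25). Alarm genes were at -0.84 (percentile 0) and -0.22 (percentile 0.41; turning to 0.0538 with doublets kept and 0.12 with cells named singly), with Cxcl10, Il6 (0.143 dorsally), Ereg (0.190 dorsally) and Areg (0.508 ventrally).

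Lists that stood out in 1 region at most made up the rest. Secretory genes were at -0.17 and -0.15 (percentiles 17.5 and 0.04; Muc4 0.390 and Reg3g 0.507 ventrally), and multiciliated genes at -0.04 and -0.30 (53.2 and 0.04; Sntn 0.417 ventrally). Fibroblast-like cells, where these transcripts should be free RNA, were lower by more (secretory -1.08 and -0.65, multiciliated -1.06 and -0.41). Handling genes were at -0.29 dorsally (percentile 1.13, or 2.59 matched on length; Fosl1 0.316, Jun 0.562) and at 0.02 ventrally (89.6). Notch genes were at -0.25 and 0.02 (18.3 and 64.2), with Notch2 lower at 0.474 and Hey1 higher at 2.36-fold dorsally. BMP and TGF-beta genes (-0.14 and -0.00; 40.6 and 50.3), p53 and senescence genes (-0.35 and 0.08; 5.49, or 1.67 matched on length, and 95.8), class II genes (-0.04 and -0.34; 28.1 and 3.44) and regional transcription factors (-0.24 and -0.05; 13.0 and 17.2) lay inside the middle 95% of random lists matched on expression. The multiciliated and class II lists crossed 0 dorsally with size factors. With the length trend taken off, the dorsal Notch list turned to 0.10 and the BMP and TGF-beta list to 0.07. Over the alternatives the dorsal secretory list reached 0.05. Class II medians ranged from -2.43 to 0.23 dorsally and from -2.01 to -0.14 ventrally.

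Some genes stood far from the control in the dorsal knockout and near it, or on its other side, ventrally. The basal keratin gene Krt14 stood at 127, 39.6, 21.4 and 83.0 CPM, or 0.168 (0.156 to 0.179) of the control dorsally and 2.09-fold (1.96 to 2.24) ventrally. The ventral value came from cluster 18, led by Krt14, which held 24 of 1555 control and 46 of 1013 knockout ventral basal-like cells and 1 and 0 dorsal ones, and without it the ventral ratio was 0.677 (0.592 to 0.773). The immediate-early transcription regulators Csrnp1 (0.208 and 0.802) and Arid5a (0.247 and 0.935), the cytokine feedback gene Socs3 (0.263 and 0.881) and Fam110c (0.286 and 0.977) were lower dorsally, and Csrnp1 (0.235 and 0.806) and Arid5a (0.302 and 0.804) had similar ratios in fibroblast-like cells, where Socs3 was less shifted (0.643 and 0.967). Higher dorsally were Gm36220 (4.66 and 0.753), the interleukin 31 receptor gene Il31ra (4.13 and 0.542), Iqcn (4.05 and 0.865), Lag3 (4.02 and 1.06) and Grik3 (3.40 and 1.17). Gm36220 (3.91 and 0.818), Il31ra (4.10 and 0.420) and Grik3 (3.34 and 1.16) were shifted alike in fibroblast-like cells, while Iqcn (0.516 dorsally) and Lag3 (1.48) were not.

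In secretory-like cells the intelectin gene Itln1, a mucus-associated lectin, was nearly absent from both knockouts: it stood at 951, 1214, 12.0 and 11.9 CPM, or 0.0127 (0.0118 to 0.0136) and 0.00984 (0.00890 to 0.0109) of the control. The secreted Tff2 (0.276 and 0.303) and Bpifb1 (0.283 and 0.462), the interferon-induced Rtp4 (0.482 and 0.466), Myc (0.286 and 0.506) and the YAP target Ccn2 (0.547 and 0.547) were also lower. The neutrophil chemokine gene Cxcl5 was higher (4.85, 4.62 to 5.08, and 2.69, 2.57 to 2.81), as were Rnf186 (2.997 and 1.77), Anxa8 (2.46 and 1.67) and Sulf2 (1.79 and 1.87). Interferon-response genes were at -0.29 and -0.65, and Isg15 (0.832 and 0.416), Ly6k (0.996 and 0.386) and Wnt4 (0.827 and 0.433) were lower mainly ventrally. Junction genes were at -0.84 dorsally (0 of 22 above 0) and -0.20 ventrally, not matched on length (Spearman correlation of ratio and length -0.38 and 0.28). Between regions Ptprz1 (6.97- and 6.77-fold), Porcn (5.23 and 5.50) and Ms4a8a (7.71 and 5.60) were dorsal, and Ccl20 (0.102 and 0.0293), Sult1c1 (0.127 and 0.0945), Clca1 (0.129 and 0.0830) and Eya4 (0.197 and 0.0905) were ventral. The secretory-like cells lay mostly in different clusters, with 47.7% of control dorsal cells in cluster 5, 67.3% of knockout dorsal cells in cluster 3, and 50.8% and 60.4% of ventral cells in cluster 4.

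Other epithelial classes shared part of these differences. In ciliated-like cells the clock-controlled Dbp (0.482 and 0.485) and Per3 (0.382 and 0.626) and the aryl hydrocarbon receptor gene Ahr (0.469 and 0.564) were lower in knockouts, and the immunoglobulin transporter gene Pigr (2.52 and 1.59) and the chaperone gene Hspa5 (1.42 and 1.75) were higher. Itln1 was less shifted in ciliated-like than in secretory-like cells, at 0.360 of the control dorsally and 0.909 (0.810 to 1.02) ventrally. Lgr6 was dorsal (10.8- and 4.61-fold) and Serpinb11 ventral (0.0218 and 0.0626). The secretory genes Scgb1a1 (56.7- and 150-fold) and Scgb3a2 (27.3 and 96.5) also differed in ciliated-like cells, where secretory-like RNA could add to them. Gland-like cells of the ventral knockout library had lower interferon-response genes (-1.18, 23 of 23 below 0) and junction genes (-0.23). Hillock-like cells of the dorsal knockout library had lower junction genes (-0.48) but higher interferon-response genes (0.47, 18 of 24 above 0). Long transcripts were lower in these cells too (Spearman correlation of ratio and length -0.40), and their lists were not matched on length.

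Fibroblast-like cells differed strongly between regions and between genotypes. Dorsal cells held more Lrat (14.2- and 11.3-fold), Bmp5 (8.46 and 6.98), Epha3 (9.67 and 6.45), Meox1 (4.41 and 7.16) and Lum (3.11 and 2.95), and ventral cells more Sfrp2 (0.0893 and 0.125), Dlk1 (0.158 and 0.159) and the proteoglycan gene Kera (0.161 and 0.0700). In the knockouts the fibrillar collagen genes Col3a1 (0.243 and 0.349), Col1a1 (0.289 and 0.385) and Col1a2 (0.397 and 0.408) and the matrix gene Postn (0.214 and 0.305) were lower, as were Dbp (0.141 and 0.111) and the Wnt genes Sfrp4 (0.108 and 0.353) and Wnt16 (0.297 and 0.397). Dpep1 (3.84 and 2.998), Rbp4 (2.46 and 2.45), Ddit4 (2.33 and 2.15), Fmo2 (2.08 and 2.31) and the clock gene Npas2 (1.83 and 2.04) were higher. These cells lie outside the lineage in which the Cre is expressed. They lay mostly in different clusters, with 50.6% and 47.8% of ventral cells of controls and knockouts in cluster 0, against 13.5% and 2.52% of dorsal cells, and 26.4% and 32.9% of dorsal cells in cluster 7, against 4.69% and 5.22% of ventral cells. Cluster 4, the largest dorsally with 32.8% and 36.4%, also held 14.6% and 18.5% of ventral cells.

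The share of basal-like cells with a high reporter signal was alike in dorsal and ventral controls and lower in both knockouts. This comparison was added after the files were seen, from the eGFP sequence among the counted features, and the reporter marks cells that passed through Ki67 expression after tamoxifen and their progeny. With cells thinned to 8000 UMIs, 45.2% (43.5 to 46.8), 43.1% (40.6 to 45.6), 24.6% (22.6 to 26.7) and 16.3% (14.01 to 18.7) of basal-like cells held at least 5 eGFP UMIs. Without thinning the shares were 54.3%, 56.8%, 40.0% and 30.2%. Dorsal minus ventral in controls was 2.08 points (-0.965 to 5.10), and knockout minus control was -20.5 points (-23.2 to -17.8) dorsally and -26.8 points (-30.2 to -23.3) ventrally. Within clusters the dorsal drop was smaller, from 48.6% to 36.6% in cluster 0 and from 31.8% to 21.7% in cluster 2, which hold most control and most knockout dorsal cells, while the ventral shares in cluster 1 were 44.1% and 16.1%. The class is a range, since 356, 141, 160 and 79 cells stood at 4 or 5 eGFP UMIs. Fibroblast-like cells, which should lack the reporter, reached 2.95%, 1.88%, 2.68% and 1.40%, although 49.1%, 47.2%, 48.3% and 40.8% of them held some eGFP UMI, against 81.4%, 87.7%, 81.8% and 76.8% of basal-like cells.

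**Figure D3:**
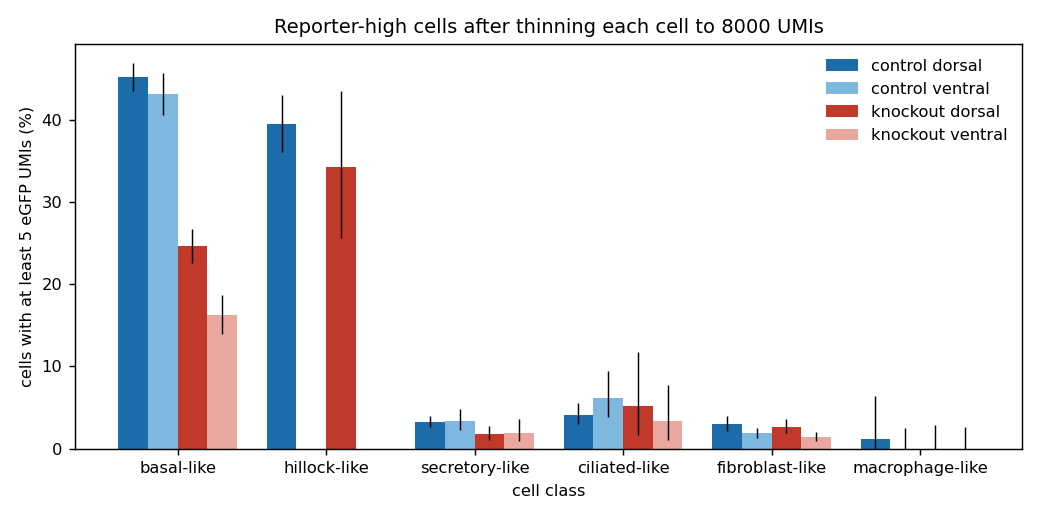
Share of cells with at least 5 eGFP UMIs after thinning to 8000 UMIs per cell (vertical axis, %) in basal-, hillock-, secretory-, ciliated-, fibroblast- and macrophage-like cells (horizontal axis). Colours mark the 4 libraries. Classes with fewer than 50 cells in a library are not drawn. Error bars are 95% intervals from counting error.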

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

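The differences in this part were picked after their values had been seen, and no explanation of them was tested, except that Krt14 was also measured without 1 cluster. Genes were sought that differed at least 1.5-fold from control to knockout in opposite directions dorsally and ventrally. H2ac18 and Il31ra were the pair that did so in all 4 classes compared (basal-, secretory-, ciliated- and fibroblast-like cells). Smaller opposite differences were not counted. H2ac18, a replication-dependent histone gene of a family whose members share near-identical sequence, which leaves its counts uncertain, stood at 4.96-fold dorsally and 0.538 ventrally in basal-like cells and at 6.73-fold and 0.499 in fibroblast-like cells. Il31ra, a cytokine receptor subunit gene, stood at 4.13-fold and 0.542 in basal-like cells and at 4.10-fold and 0.420 in fibroblast-like cells. Genes that move alike in epithelial and in fibroblast-like cells of the same library set whole libraries apart, and the difference was not tested further.

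Gm36220 (4.66-fold dorsally, 0.753 ventrally) and Iqcn (4.05-fold and 0.865) were higher in basal-like cells of the dorsal knockout library and not of the ventral one. The keratin gene Krt14, a marker of basal cells, was at 0.168 of the control dorsally and at 2.09-fold ventrally, so its dorsal and ventral knockout libraries stood on opposite sides. Without a small ventral cluster that Krt14 leads (24 control and 46 knockout cells) the ventral value was 0.677, so the higher value belongs to that cluster. Whether these differences belong to the mice, to the region or to the handling of single libraries was not tested.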

How the results depend on the processing

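Alternatives set after the results were seen included at least 3 and at least 8 eGFP UMIs, unthinned reporter shares, the mitotic gene count and the surface epithelium. Others were Ctnnb1 relative to fibroblast-like cells, the length trend, single clusters and Krt14 without cluster 18. No paired analysis was possible because each group was 1 library and the labels do not match dorsal and ventral tissue to the same mice. Of the alternatives for the main results, 88 stayed near their value, 25 moved and 5 turned a value that had been beyond counting error, and of the others 339 stayed, 125 moved and 5 turned such a value. Values near 0 included, 14 of 118 and 39 of 469 alternatives lay on the other side. All 20 named genes of each comparison in basal-like cells kept their side in the 6 settings tried (filter, doublets, both resolutions, cells named singly and size factors). Reporter-high knockout minus control moved to -15.6 points dorsally and -20.1 ventrally with at least 8 eGFP UMIs and to -14.3 dorsally without thinning, and dorsal minus ventral moved to -2.56 without thinning and 5.98 with cells named singly. Over all 8 reporter alternatives, knockout minus control lay between -22.4 and -14.3 points dorsally and between -26.8 and -20.1 ventrally. The cycling share moved to -19.8 (dorsal minus ventral) and 13.5 points (knockout dorsally) without thinning, so depth limits this share. With the mitotic genes, also on thinned cells, it moved to 3.94 and -3.14 points, so the share depends on the genes and cut used as well. Ctnnb1 dorsally moved to 0.775 with size factors, 0.723 with thinned cells and 0.991 relative to fibroblast-like cells, and ventrally to 0.962 by the latter. Among the 70, 5, 25 and 6 basal-like cells without a proliferation gene UMI, Ctnnb1 was at 0.817 and 1.17, and Wnt targets at 1.00 (dorsal to ventral), -1.10 and 2.12 (knockout, dorsally and ventrally), where 5 and 6 cells are too few to read. Wnt targets dorsally in knockouts moved to -0.24 with the length trend taken off and -0.39 in cluster 2 alone, and dorsal to ventral to -0.49 with cells named singly. The basal-like share, dorsal minus ventral, moved to 3.32 points (strict filter), 2.76 (doublets kept), 1.93 (resolution 2), 1.95 (cells named singly) and -6.52 (surface epithelium), and knockout minus control to 16.3, 15.7 and 5.43 dorsally with doublets kept, resolution 2 and cells named singly and to 8.32 ventrally with the surface epithelium. With doublets kept, alarm genes turned to -0.0758 (dorsal to ventral, controls) and 0.0538 (knockout ventrally). With cells named singly, Wnt ligands turned to 0.0101 (knockout dorsally) and alarm genes to 0.12 (knockout ventrally). Without cluster 18, Krt14 turned to 0.677 (knockout ventrally). The cause was not tested for the values that moved.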

Other observations

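The weighing below used tests of which the transcript length and hour of collection tests were written before their results were seen, and all others after. Reporter-high basal-like cells were richer in division and hillock RNA than reporter-low cells, but not in every library. In the control dorsal, knockout dorsal and knockout ventral libraries the proliferation list stood higher in reporter-high cells, at medians of 0.77 (27 of 30 genes above 0), 3.20 (30 of 30) and 0.98 (26 of 27), with Mki67 at 1.74-, 21.02- and 4.85-fold. In control ventral cells it stood lower, at -1.33 (28 of 29 below 0), with Mki67 at 0.355 and Top2a at 0.268. Cluster 16, with Hmgb2, Ube2c and Top2a among its leading genes, held 113, 3, 24 and 1 reporter-high and 26, 6, 5 and 1 reporter-low cells. The ventral values could therefore rest on few cells, and division genes found in the same cells are not independent. The list was not measured without this cluster. Hillock and squamous genes were higher in reporter-high cells of all 4 libraries (0.69, 0.27, 1.04 and 0.39), with Krt6a at 2.81-, 2.41-, 5.51- and 2.09-fold.

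Krt14 RNA was concentrated in reporter-high cells dorsally, at 9.23-fold (8.42 to 10.1) in controls and 90.5-fold (53.6 to 166) in knockouts, and was lower in them ventrally, at 0.410 and 0.081. The ventral value of controls goes with cluster 18, led by Krt14 and Krt17, which held 2 reporter-high and 14 reporter-low control cells and 1 and 31 knockout cells. Without it Krt14 stood at 1.19-fold (0.993 to 1.43) in ventral controls and still lower, at 0.197 (0.0886 to 0.384), in ventral knockouts. The keratin gene Krt17 was higher in dorsal reporter-high cells, at 1.85- and 3.07-fold, and nearly even ventrally without that cluster, at 0.956 and 1.03. The basal transcription factor gene Trp63 was nearly even, at 0.899, 0.864, 0.860 and 0.954.

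Lower junction, matrix adhesion and Wnt target genes in dorsal knockout basal-like cells were weighed against transcript length and against an effect in basal-like cells alone. Among random lists matched on length the junction list stood at percentile 0, matrix adhesion at 0.26 and Wnt targets at 1.13, so length is not the whole cause, although taking off its trend moved their medians from -0.97, -0.67 and -0.52 to -0.58, -0.29 and -0.24. The 15 Wnt targets that fibroblast-like cells hold at 0.5 or more of the basal-like level, such as Axin2, Lef1 and Apcdd1, had a median of -0.79 in those cells, which speaks against an effect in basal-like cells alone. For junction genes the values in fibroblast-like cells could not tell an effect in basal-like cells alone from a shift of the whole library. Only 4 genes (Vcl, Afdn, Tjp1 and Cldn1, median -0.47) reach that level in fibroblast-like cells. The median of -1.04 over all 18 genes measured there could come from free epithelial RNA. Junction genes were lower in dorsal secretory-like and hillock-like cells too, so the drop was not seen in basal-like cells alone. The lists of those classes were not matched on length. Other differences in RNA quality between the libraries were not tested.

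Clock genes differed between knockout and control libraries in many classes, and an hour of collection that differed between genotypes is a possible source. Output genes such as Dbp and Nr1d1 minus the Npas2 group was at -0.80 in dorsal hillock-like cells, and -1.48 in ventral gland-like cells, which is consistent with a different hour of collection. Fibroblast-like cells, outside the Cre lineage, had -1.36 dorsally and -1.40 ventrally, which is against an effect in basal-like cells alone. Basal-like cells were at 0.03 dorsally and -0.15 ventrally, with output genes on both sides of 0, so their clock genes lack the pattern that a different hour should give in every class. Nor was the Npas2 group higher in every other class. Of its genes, 0 of 4 were above 0 in macrophage-like cells of both regions and 1 of 5 in dorsal ciliated-like cells, against 5 of 5 in ventral secretory-, ciliated- and chondrocyte-like cells. The hour of collection is not given in the sources used here.

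The lower share of reporter-high basal-like cells in the knockouts was weighed against free eGFP RNA, less eGFP in every labelled cell and fewer dividing cells. Free RNA does not account for the drop, since only 2.95% of control dorsal fibroblast-like cells were reporter-high. With control eGFP UMIs thinned by 1 factor down to the reporter-high shares of the knockouts, cells with 2 to 4 eGFP UMIs would be 27.8% dorsally and 28.9% ventrally, against 19.2% (17.4 to 21.2) and 17.5% (15.2 to 20.0) in the knockouts, so an equal loss in every labelled cell is not the whole cause. Fewer dividing basal-like cells could also lower the share, as the proliferation list was at -0.66 in the ventral knockout, but this cannot be told apart because dorsal and ventral controls had like reporter shares despite a proliferation list at 1.73. Uneven loss of eGFP and less recombination in the knockouts, which carry a further floxed allele, were not tested.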
